A study of Mus musculus with 6 samples.

How the data were processed

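Gene expression was measured in mouse embryos at embryonic day 11.5, in tissue dissected around the inner ear (the otic vesicle, the epithelial sac that forms the inner ear, with the periotic mesenchyme around it). Each array held RNA from a pool of 3 embryos of 1 genotype, with left and right ears together, and 300 ng of total RNA was labelled per array, per the labels' protocols. The arrays were 1-colour Affymetrix Mouse Genome 430 2.0 arrays with 45101 probe sets, and there were 3 arrays of each genotype. Groups were taken from the genotype labels. Mest-KO pools carried a conditional Tbx1 knockout made with T-Cre, which is active in mesoderm, and control pools were heterozygous for the same conditional allele.

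The deposited values were intensities on a linear scale, made with Affymetrix Expression Console 1.1 per the submitters' processing notes. The summarization algorithm and the background correction are not given in the sources used here. The mean intensity without the lowest and highest 2% of probe sets was 500.002 on every array, so each array had been scaled to a common level, and the values were not quantile normalized. Such scaling fixes the mean of each array, so a change shared by most genes would not show. Array medians ran from 59.954 to 70.6371. Scanner files were not used here, so background was judged from 27 probe sets for bacterial transcripts that were not spiked in, whose highest intensity on any array was 11.1922. A gene at or below that level on every array of a group was given only a bound. For arrays, the number of arrays limits the precision.

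The 64 control probe sets were left out. Of the 45101 probe sets, 34945 were listed with 1 gene symbol, 932 with several genes and 9160 were not listed, in a table of the platform's annotation. Symbols were checked through the Entrez ID against RefSeq gene names of GRCm38.p6, which changed 0 symbols and lacked the Entrez ID of 204 probe sets. No coordinates are printed, because the arrays name no genome build. Intensities were taken as log2(value + 16), and a log2 difference on this scale understates the change of dim genes. Each gene was represented by its probe set with the highest mean over all 6 arrays, and genes were kept where that mean was above the 30th percentile of all probe sets, which left 14170 of 18193 genes.

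Mest-KO was compared with control by a linear model with genotype as the only term in limma 3.58.1 (R 4.3.3), with moderated variances that followed the mean level (eBayes with trend), two-sided, and Benjamini-Hochberg adjustment at 0.05. Errors given with log2 differences are standard errors of that fit, and intensities are given as mean ± SD over 3 arrays. The labels call the 3 arrays of a group biological replicates, each a pool of separate embryos. For single values, exact permutation tests of 3 against 3 were run, which cannot give a p below 0.1. A set of 29 gene lists (pathways, tissue parts, gene families, cell types that the dissection could hold, sample handling, sex makeup and genes near Tbx1) was fixed before the data were examined. The 28 lists with at least 3 tested genes were tested with limma's camera with a preset correlation of 0.01, and again with an estimated correlation and with fry, for change in one direction and in either, each adjusted over the 28 lists. Of 620 different genes in the lists, 575 had a probe set with 1 gene name and 516 were tested.

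The genes named were chosen by a rule fixed at the same time. Tbx1 came first. In each direction the 12 genes with the largest log2 difference past the threshold were named, and where fewer passed, the remaining places went to genes with the smallest p whose groups did not overlap, given as values. Predicted or unnamed transcripts were named only where fewer than 8 others were left. For each list, members past the threshold over all genes or over the list alone were eligible, and otherwise up to 4 members with the smallest p. Over the list alone, p was adjusted within each list separately, with no adjustment over the 28 lists. A gene in several lists could therefore pass in some and not in others. Such calls are not controlled at 0.05 across lists or over all genes. Pou3f4, Isl1 and Gata3, for example, had limma adjusted p of 0.260, 0.310 and 0.361 over all genes. Genes named outside this rule are marked as chosen later.

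The steps were tested on simulated data with the real means and spreads of the 14170 genes, in which 200 genes were changed between Mest-KO and control. Of the genes changed 1.5-fold, 31 of 67 were recovered, of those changed 2-fold, 56 of 67, and of those changed 4-fold, 64 of 66. Of 164 genes called, 13 (7.93%) had not been changed. All 5 simulated lists of 20 genes shifted by 0.4 on the log2 scale were called, and 0 of 20 unshifted lists. The simulated genes were independent of each other, unlike real genes.

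Alternatives chosen before the data were examined were quantile normalization, centring each array on its median, no filter or a filter at the 50th percentile, the mean of all probe sets of a gene, every probe set tested separately, eBayes without trend, ordinary least squares, array weights, the replicate number as a block, a Y-linked covariate, log2 offsets of 1 and 64, other thresholds, and leaving out each array. A covariate for hindbrain neural tube genes and a fit without control 1 and control 3 were added after seeing the data.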

Results

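Microarray profiles of dissected ear tissue were analysed from 6 arrays, 3 from control pools and 3 from Mest-KO pools, in which Tbx1 had been deleted with a mesodermal Cre. Tbx1 encodes a T-box transcription factor made in both the otic epithelium and the surrounding mesenchyme. The comparison asked which genes of the otic vesicle and periotic mesenchyme changed when Tbx1 was lost from mesoderm. The arrays resembled each other closely. Correlations of log2 intensities across the 14170 genes kept were between 0.991 and 0.993 within groups and between 0.987 and 0.992 across groups.

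The Tbx1 transcript itself did not differ detectably. Its only probe set read 512.8 ± 61.1 in control and 502.8 ± 85.4 in Mest-KO (SD, n = 3 arrays each; exact permutation p = 0.9). The log2 difference was -0.03 ± 0.14, with a 95% interval from -0.35 to 0.28 (limma, adjusted p = 0.967). This value does not check the labels. Tbx1 is also made in otic epithelium, where the Cre does not act, the controls were heterozygous, and the sources used here do not say whether the probe set lies in the deleted part of the gene.

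Among the 14170 genes tested, 12 rose and 9 fell in Mest-KO (limma, adjusted p under 0.05). Hand2, a transcription factor of branchial arch, limb and heart mesenchyme, rose most, from 21.8 ± 10.9 to 145.6 ± 44.2 (log2 difference 2.10 ± 0.24, adjusted p = 0.0105). Over the alternatives its difference ranged from 1.06 to 2.75 and that of Foxl2os from 1.46 to 2.17, so Hand2 did not rise most in each. Neurog1, a transcription factor that starts neuron formation in the otic vesicle, rose from 187.6 ± 9.79 to 449.0 ± 124.4 (1.15 ± 0.19, adjusted p = 0.0478). Pou4f1, a transcription factor of sensory neurons, rose from 1347 ± 92.6 to 2031 ± 26.9 (0.59 ± 0.08, adjusted p = 0.0256). Meox1, a homeobox gene of paraxial mesoderm, rose by a log2 difference of 1.15 ± 0.18. Sst, encoding the peptide somatostatin, rose by 1.61 ± 0.23, and Foxl2os, a noncoding transcript next to the forkhead gene Foxl2, by 1.68 ± 0.20. Foxl2 itself, chosen after its value was seen, differed by 0.94 ± 0.17 and did not pass (adjusted p = 0.0911). The other genes that rose were Pex5l (1.20 ± 0.17), Mirg, a noncoding RNA of the imprinted Dlk1-Dio3 domain (0.91 ± 0.13), Npr2, a receptor for C-type natriuretic peptide (0.75 ± 0.11), the integrin gene Itga4 (0.61 ± 0.08), Postn, encoding the matrix protein periostin (0.55 ± 0.08), and 1 predicted transcript. Other probe sets of these genes did not all agree. For Itga4 a probe set of good signal differed by -0.05 ± 0.13 and 2 others by 0.27 ± 0.16 and 0.32 ± 0.16. A second probe set differed by 0.16 ± 0.18 for Mirg, 0.54 ± 0.22 for Neurog1, 0.65 ± 0.27 for Pou4f1 and 0.81 ± 0.27 for Hand2, and 3 of Pex5l by 0.33 to 0.39.

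Clu, encoding the secreted chaperone clusterin, had the smallest p of all genes and fell from 1733 ± 158.6 to 606.7 ± 17.3 (log2 difference -1.49 ± 0.10, adjusted p = 0.000143). Foxa1, a forkhead transcription factor of endoderm, fell from 350.3 ± 77.8 to 126.9 ± 13.9 (-1.34 ± 0.17, adjusted p = 0.0191). Tafa4, encoding a secreted peptide, fell by 1.30 ± 0.14 on the log2 scale, Fam162b by 1.48 ± 0.18, and Anxa8, encoding an annexin, by 1.18 ± 0.19. The expressed sequence AI606473 fell by 2.83 ± 0.40. AI506816 fell from 348.3 ± 171.9 to 8.63 ± 8.96, and because Mest-KO 2 and 3 read below the highest unspiked control, the size of its log2 difference (-3.84 ± 0.33) depended on background and ranged from -5.51 to -2.43 over the alternatives. Skor1, a corepressor made in neural tube interneurons, fell from 544.7 ± 352.2 to 24.9 ± 5.98 (-3.46 ± 0.49, adjusted p = 0.0256), but control 2 read only 138.0 where control 1 and control 3 read 746.3 and 749.8. Hoxb1, a homeobox gene of the hindbrain, was at or below the unspiked controls in all 3 Mest-KO arrays and averaged 45.1 ± 18.9 in control, at least 2.18-fold higher (adjusted p = 0.0478). AI606473 neighbours the LIM homeobox gene Lhx8, which differed by -2.14 ± 0.37 without passing (adjusted p = 0.0742). Hhip, encoding a hedgehog-binding membrane protein, differed by -0.92 ± 0.15 (adjusted p = 0.0547) and Mup10, one of a family of near-identical genes and therefore uncertain, by -1.46 ± 0.26 (adjusted p = 0.0802).

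**Figure D1:**
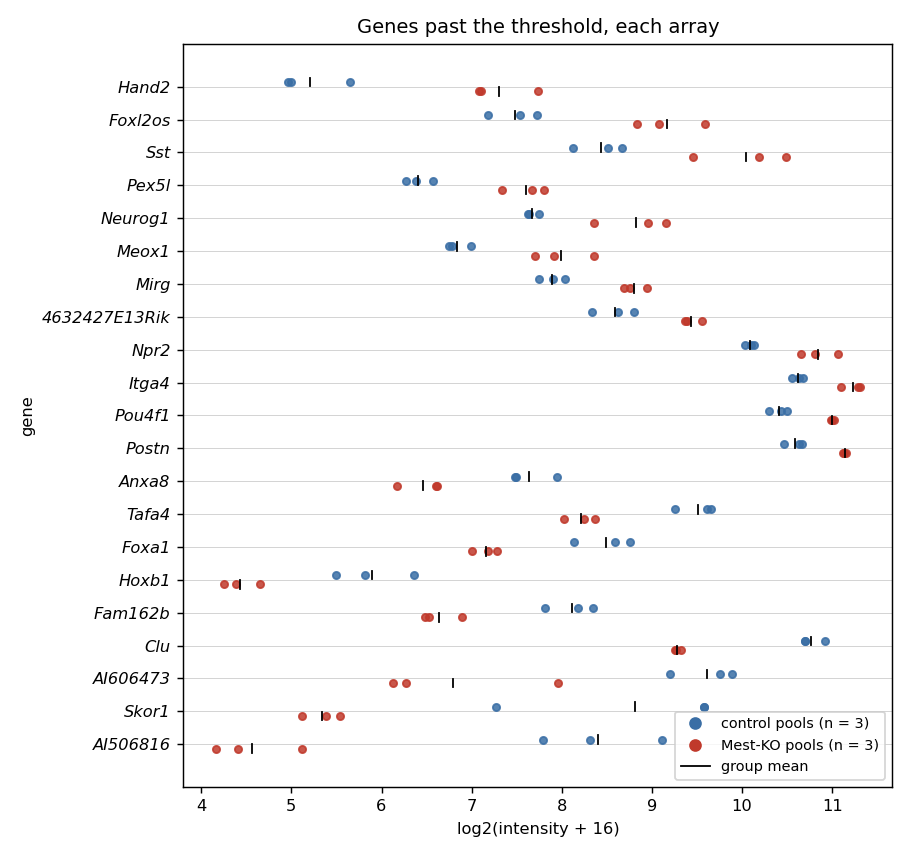
Log2 of intensity plus 16 (horizontal axis) on each array for the genes past the threshold (vertical axis), with control pools in blue, Mest-KO pools in red and group means as black bars. The groups do not overlap for any of the 21 genes, and Skor1 in control is spread from 138.0 to 749.8 in intensity.

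At an unadjusted p under 0.05, 1271 genes differed, 812 higher and 459 lower in Mest-KO. Of these, 229 also differed at least 1.5-fold, 107 higher and 122 lower. The values of the groups did not overlap for 14.5% of genes (1320 higher and 740 lower), where chance gives 10% for 3 arrays against 3. The count of 21 depended strongly on single arrays and on the kind of scaling. It was 2, 82 and 6 without control 1, 2 and 3, and 3, 9 and 21 without Mest-KO 1, 2 and 3, and with arrays centred on their medians 78 genes passed, 22 higher and 56 lower. With quantile normalization 10 genes passed higher and 11 lower, and 19 of the 21 stayed past the threshold. The single calls depended on these choices unequally. Of 23 alternatives, Clu passed in 22, AI506816 in 21, Foxl2os and Tafa4 in 18, Fam162b in 16, Foxa1 in 14, Sst in 13 and Hand2 in 15 of 22, and the other 13 genes in 11 or fewer, with Postn and Anxa8 at 9, Neurog1 and Meox1 at 8 and Hoxb1 at 7 of 22.

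Genes of neurons and cranial ganglia were higher as a group. Of 26 tested, 21 were higher in Mest-KO, 1 rose at the threshold over all genes and 9 rose when adjusted over the list alone, with a median log2 difference of 0.21 (camera, adjusted p = 2.55e-08; adjusted p = 0.164 with an estimated correlation). Besides Pou4f1, the transcription factors Neurod1 (0.34 ± 0.07), Neurod4 (0.58 ± 0.14) and Isl1 (0.27 ± 0.08) rose over the list alone, as did the neurofilament gene Nefm (0.27 ± 0.08), the RNA-binding protein genes Elavl3 and Elavl4, the neurotrophin receptor gene Ntrk3 (0.51 ± 0.16) and Eya2. Of 20 alternatives, these calls were lost in 13 for Ntrk3, 11 for Isl1 and Elavl3, 10 for Eya2 and 9 for Nefm. They were lost in 8 for Elavl4, 5 for Neurod1, 4 for Neurod4 and 0 for Pou4f1. In the list of prosensory and neurosensory otic genes, 5 rose over the list alone, namely Pou4f1, Neurog1, Neurod1, Isl1 and Prox1 (0.41 ± 0.12). Pou4f1, Neurod1 and Isl1 are in the neuron list too, so their calls are not separate evidence. Gata3, a transcription factor of the otic epithelium, fell over the list alone (-0.62 ± 0.21; limma, adjusted p = 0.361 over all genes). Of all members 14 were higher and 9 lower. Sox2 (0.003 ± 0.15), Jag1 (0.06 ± 0.07) and Atoh1 (-0.69 ± 0.32), chosen after their values were seen, did not pass. The groups overlapped for Gata3, which did not pass over the otic epithelium list alone. Of 20 alternatives, the call in the prosensory list was lost in 13 for Gata3 and Isl1 and 12 for Prox1. It was lost in 4 for Neurod1, 1 for Neurog1 and 0 for Pou4f1. The list of 23 genes did not pass (median 0.01; adjusted p = 0.143), but over the alternatives its adjusted p ranged from 0.0109 to 0.546 and it passed in 5, with the filter at the 50th percentile, with the Y-linked covariate (adjusted p = 0.0336), without control 3, and, both chosen after seeing the data, with the neural tube list as a covariate (adjusted p = 0.0118) and without control 1 and control 3. Neural crest and glia genes were higher as well (median 0.08 over 17 genes; adjusted p = 0.0104, and 0.187 as adjusted p with an estimated correlation), but the list did not pass in 8 of 21 alternatives, among them the filter at the 50th percentile, the mean of all probe sets, without control 1 and without Mest-KO 3, and its median ranged from 0.02 to 0.18. Their 4 members past the threshold over the list alone were Hand2, Sox10 (0.41 ± 0.08), Ngfr (0.41 ± 0.11) and Alx1 (0.50 ± 0.14).

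The hedgehog pathway list passed toward lower levels in Mest-KO, but its members went both ways, with 10 lower, 6 higher and a median of -0.09. Of the 16 tested, 0 passed over all genes, while 6 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 0.00055; adjusted p = 0.176 with an estimated correlation). The ligand gene Shh fell from 742.8 ± 226.2 to 257.7 ± 108.3 (-1.50 ± 0.27). Hhip, the forkhead genes Foxf1 (-0.96 ± 0.19) and Foxf2 (-0.66 ± 0.16), Sostdc1 (-0.64 ± 0.14) and the receptor gene Ptch1 (-0.25 ± 0.06) also fell, while the ligand gene Dhh rose (0.53 ± 0.16). Gli1, a direct target of the pathway chosen after its value was seen, differed by -0.07 ± 0.13. In the pharyngeal endoderm list, Foxa1, Shh, Pax1 (-1.47 ± 0.30) and Fgf15 (-1.11 ± 0.30) fell over the list alone and the other 7 of 11 genes did not pass (list adjusted p = 2.81e-05; adjusted p = 0.176 with an estimated correlation). Among transcription factors of periotic mesenchyme, Foxf1, Foxf2, Tbx15 (-0.36 ± 0.10) and Pou3f4, whose loss causes deafness (-0.76 ± 0.21), fell over the list alone and Meox1 rose (25 genes, median -0.06; adjusted p = 0.0104, and 0.356 as adjusted p with an estimated correlation). The groups overlapped for Pou3f4. Of 20 alternatives, the call in this list was lost in 10 for Tbx15, 6 for Foxf2, 5 for Pou3f4, 3 for Foxf1 and 1 for Meox1. The periotic mesenchyme list did not pass without Mest-KO 1, and its median ranged from -0.17 to -0.02 over the alternatives.

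Genes of BMP and TGF-beta signalling were lower (28 genes, 20 of them lower, median -0.18; adjusted p = 2.81e-05, and 0.187 as adjusted p with an estimated correlation). Over the list alone, 6 fell and 0 rose, among them the antagonist genes Grem1 (-1.20 ± 0.28), Chrdl1 (-0.56 ± 0.13) and Fst (-0.55 ± 0.13) and the target genes Msx1 (-0.46 ± 0.11) and Msx2 (-0.43 ± 0.10). Those that fell were therefore both inhibitors and targets of the pathway. The WNT list was lower too (30 genes, median -0.09; adjusted p = 0.00175, and 0.35 as adjusted p with an estimated correlation), with Frzb (-0.46 ± 0.09), an inhibitor, Rspo2 (-0.49 ± 0.11), an enhancer, and Wnt7b (-0.62 ± 0.16), a ligand, falling over the list alone.

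Genes of the hindbrain neural tube, which lies beside the otic vesicle, differed most in level (19 genes, 18 lower, median -1.09; camera, adjusted p = 7.11e-12; adjusted p = 0.356 with an estimated correlation). Over the list alone 10 fell, among them Neurog2 (-1.89 ± 0.43), Sox1 (-1.83 ± 0.45) and Lhx1 (-1.75 ± 0.52). The list mean did not separate the groups. Relative to the mean of the 6 arrays it was 0.92, -0.33 and 0.88 in control 1, 2 and 3 and -0.62, -0.04 and -0.80 in Mest-KO 1, 2 and 3 (exact permutation p = 0.2). These control differences ran alongside the endoderm list, which read 0.41, 0.01 and 0.41 in control 1, 2 and 3, the hedgehog list (0.16, 0.08 and 0.16) and Skor1. The sex markers split the controls in the same way, with the Y-linked list at -0.49, 0.43 and -0.43 in control 1, 2 and 3 and 0.26, 0.23 and 0.01 in Mest-KO, and Xist at 0.42, -0.29 and 0.41 and -0.09, -0.07 and -0.37. With the Y-linked mean as a covariate the median of the neural tube list went from -1.09 to -0.59, and 6 genes fell over the list alone where 10 had. With the neural tube list as a covariate, chosen after seeing the data, the hedgehog, endoderm, BMP, neuron, erythroid and cell cycle lists kept an adjusted p under 0.05 and the WNT, periotic mesenchyme and neural crest lists did not. Besides the prosensory list, 4 lists came to pass, surface ectoderm (median -0.34), blood endothelium (0.23), smooth muscle (0.29) and Hox genes (0.37). The neuron median went from 0.21 to 0.09, the BMP median from -0.18 to -0.13, the endoderm median from -0.28 to -0.15 and the erythroid median from -0.18 to -0.16. The hedgehog and cell cycle medians became larger in size, from -0.09 to -0.15 and from -0.04 to -0.11. Calls over the list alone went from 9 to 2 for neurons, from 6 to 0 for BMP, from 4 to 1 for endoderm and from 7 to 1 for hedgehog, where the differences were a median of 0.83, 0.78, 0.71 and 0.86 times those before and the errors 1.42, 1.42, 1.32 and 1.44 times. Msx1, for example, went from -0.46 ± 0.11 to -0.39 ± 0.16 and Fst from -0.55 ± 0.13 to -0.40 ± 0.17. Over all genes 6 passed, 5 of them among the 21 (Clu, AI506816, Foxl2os, Sst and Tafa4). The 16 lost included Hand2, Neurog1, Pou4f1, Meox1, Foxa1, Skor1 and Hoxb1. Of these, Pou4f1 went from 0.59 ± 0.08 to 0.68 ± 0.12 and Foxa1 from -1.34 ± 0.17 to -1.10 ± 0.23. Without control 1 and control 3, 5 genes passed, 4 of them among the 21.

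**Figure D2:**
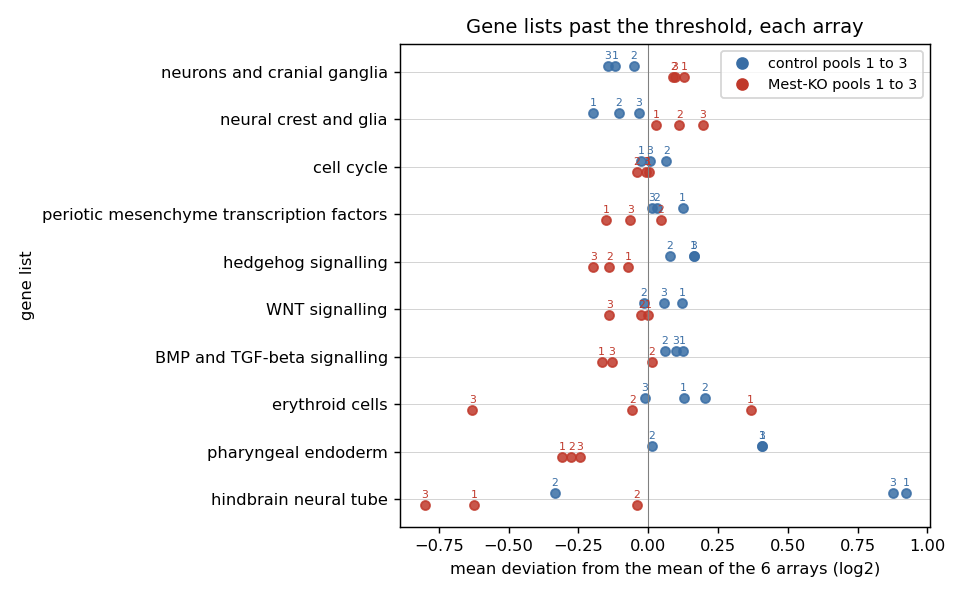
Mean log2 deviation of each gene list past the threshold from the mean of the 6 arrays (horizontal axis), for control pools (blue) and Mest-KO pools (red) with the pool number beside each point. The neuron, neural crest, BMP, hedgehog and endoderm lists separate the groups, while the hindbrain neural tube list is at -0.33 in control 2 and -0.04 in Mest-KO 2.

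Erythroid genes were lower on average (16 of 16 genes, median -0.18; adjusted p = 0.00175, and 0.615 as adjusted p with an estimated correlation). This rested on Mest-KO 3, whose list mean was -0.63 while that of Mest-KO 1 was 0.37, and without Mest-KO 3 the median was 0.05. Cell cycle genes passed narrowly (34 genes, median -0.04; adjusted p = 0.0466, and 0.487 as adjusted p with an estimated correlation), with 0 members past the threshold over the list alone. The cell cycle list did not pass in 8 of 21 alternatives, with quantile normalization, no filter, eBayes without trend, array weights, an estimated correlation and directional fry, without control 2 and without Mest-KO 2, and its adjusted p ranged from 0.00034 to 0.546.

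The 14 tested genes of retinoic acid metabolism did not shift one way as a list (median 0.16; camera, adjusted p = 0.32). Over the list alone, Aldh1a2 (0.45 ± 0.14) and Aldh1a3 (0.43 ± 0.12), encoding enzymes that make retinoic acid, rose and Cyp26b1 (-0.65 ± 0.20), encoding an enzyme that breaks it down, fell, and 0 passed over all genes. Each kept its direction, but of 20 alternatives Aldh1a2 lost this call in 13, Aldh1a3 in 14 and Cyp26b1 in 12, and 0 of the list passed with the replicate block or with the Y-linked covariate. Aldh1a2 went from 117.4 ± 7.62 to 166.1 ± 14.8 and Cyp26b1 from 213.6 ± 35.8 to 132.2 ± 38.9. Another degrading enzyme gene, Cyp26a1, differed by 0.28 ± 0.12 without passing. Of 26 retinoic acid receptors and response genes, Hoxb1 fell and Hoxb5 rose (1.05 ± 0.25) over the list alone, and the list did not pass (adjusted p = 0.32). In the T-box family Tbx22 (-1.18 ± 0.29) and Tbx15 fell over the list alone and the list did not pass (adjusted p = 0.567). Tbx15 lost this call in 9 of 20 alternatives and Tbx22 in 7 of 19. Sox10 rose and Otx1 (-0.79 ± 0.20) fell over the list alone among 30 genes of the otic epithelium, where the list did not pass either (adjusted p = 0.567).

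**Figure D3:**
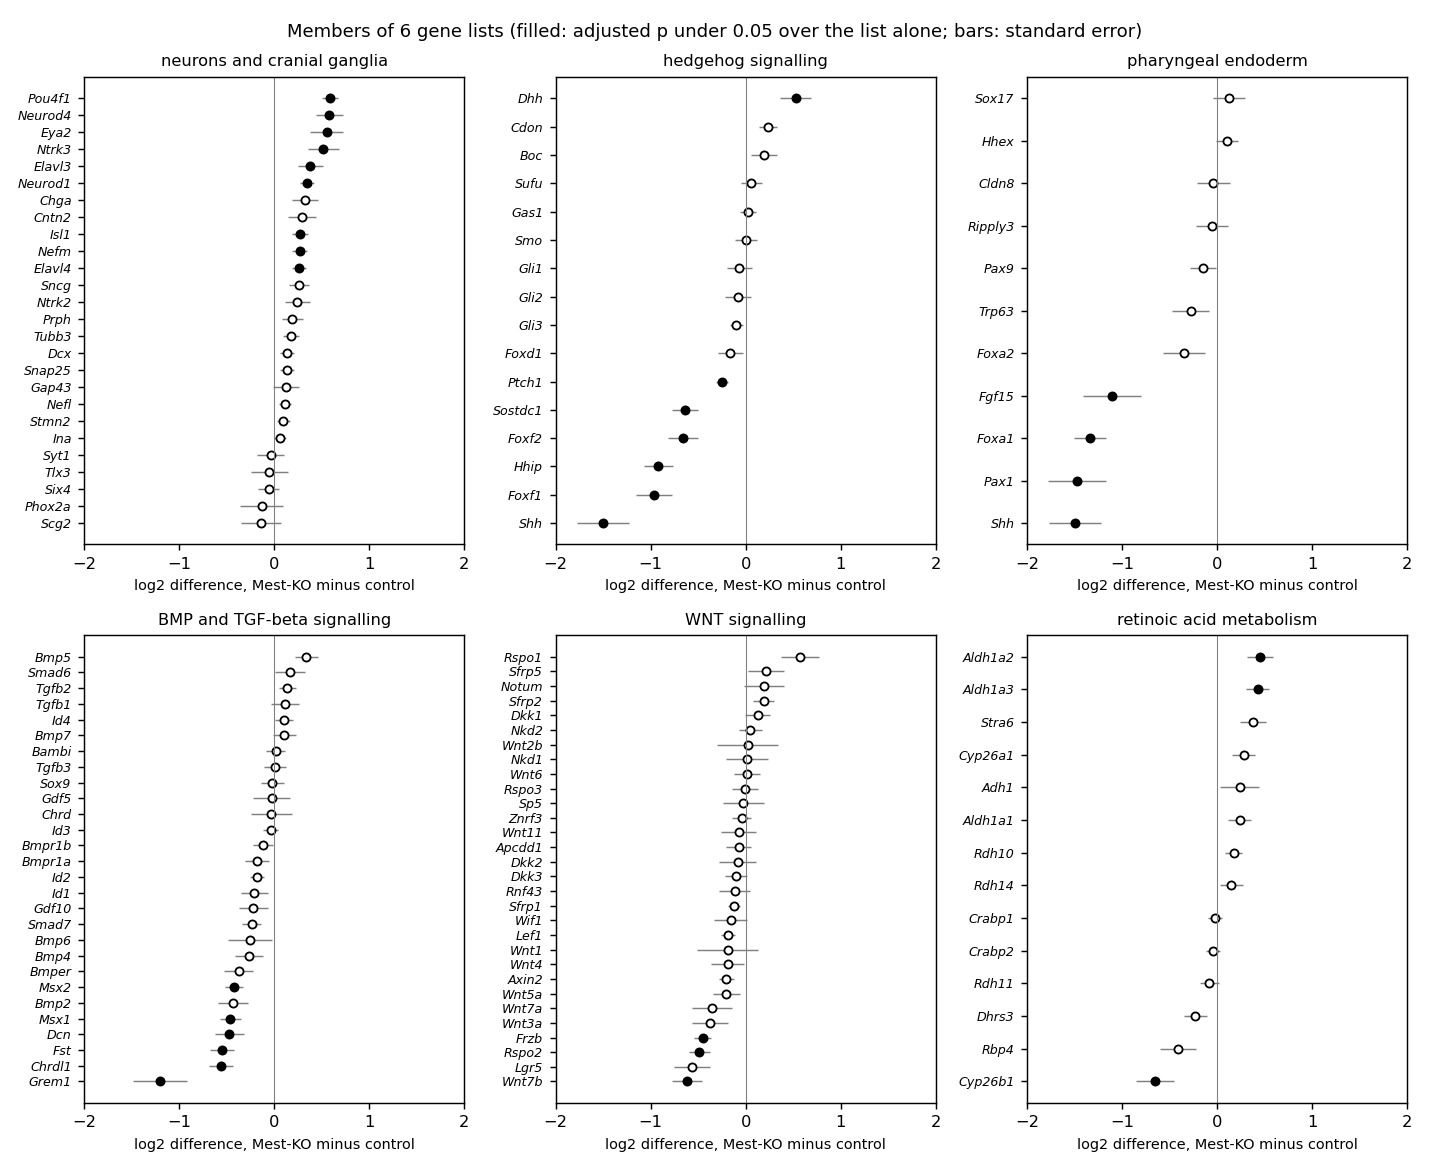
Log2 difference of Mest-KO minus control (horizontal axis, bars are standard errors of the fit from 3 arrays per group) for each tested member (vertical axis) of 6 gene lists. Filled points passed the threshold over their list alone, such as Aldh1a2, Aldh1a3 and Cyp26b1 in retinoic acid metabolism, and open points did not.

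The lists for FGF signalling, cartilage and otic capsule, Hox genes, head muscle, blood endothelium, lymphatic endothelium, macrophages, surface ectoderm, smooth muscle and pericytes, hypoxia and glycolysis, immediate early and heat shock genes and genes next to Tbx1 did not pass, with adjusted p from 0.0594 for surface ectoderm to 0.61 for Hox genes. Over 21 alternatives, however, surface ectoderm passed in 10, 8 of them chosen before the data were examined, blood endothelium in 6, head muscle and macrophages in 4 each, cartilage and hypoxia in 3 each, Hox genes and smooth muscle in 2 each, and the other 4 in 0. A test for change in either direction (fry, mixed), which does not compare a list with other genes, had an adjusted p under 0.05 for 13 lists, of which 6 did not pass with camera, those of retinoic acid metabolism (adjusted p = 0.00126), retinoic acid receptors and response genes, prosensory and neurosensory genes, FGF signalling, Hox genes and lymphatic endothelium. Of the lists that did not pass, over the list alone, the lymphatic list had Pdpn lower (-0.27 ± 0.08) and Prox1 higher, surface ectoderm had Tfap2c higher (0.61 ± 0.16) and Sostdc1 lower, and the Hox list had Hoxb1 lower and Hoxb5 higher. The sex makeup of the pools varied. Eif2s3y, a Y-linked gene, read 1373 ± 522.8 in control and 1965 ± 97.3 in Mest-KO, and Xist, made from the inactive X chromosome, read 2474 ± 642.1 and 1888 ± 215.1 (SD, n = 3 arrays each; exact permutation p = 0.3 for both). Eif2s3y rose over the list alone (log2 difference 0.57 ± 0.19), while the Y-linked list did not pass (adjusted p = 0.137), except with array weights and without control 2. Of 2 other Xist probe sets, 1 was lower without overlap of the groups (-0.71 ± 0.22) and 1 differed by -0.07 ± 0.23.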

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

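The alternatives with the neural tube covariate and without control 1 and control 3 were chosen after the results were seen, and all others before. None of the 21 genes changed direction under any alternative run. Their groups did not overlap, so leaving out or weighting arrays or changing the offset could not turn a direction. Alternatives that changed only the filter, the test or the threshold left the differences the same. Clu stayed past the threshold in 22 of 23 alternatives, the exception being ordinary least squares. An adjusted p under 0.10 passed all 21 by definition. The count of genes past the threshold moved widely. It was 78 with arrays centred on their medians, 2 with no filter, 6 with the mean of all probe sets, 1 with eBayes without trend, 41 at an adjusted p under 0.10 and 0 with ordinary least squares, where 1128 genes had an unadjusted p under 0.05, against 1271 in limma. It was 6 with the neural tube covariate and 5 without control 1 and control 3, and between 2 and 82 when single arrays were left out. No pairing by replicate number was seen, with correlations of -0.03, -0.11 and -0.15 between the deviations of same-numbered arrays. These few values cannot exclude a shared litter or day, because the deviations were taken from group means of 3 arrays and sum to 0. With the replicate number as a block, 9 genes passed, 8 of them among the 21. With the Y-linked covariate, 9 genes rose and 6 fell, and 12 of the 21 stayed past the threshold. The 9 lost were Pex5l, Neurog1, Meox1, Mirg, Npr2, Itga4, AI606473, Hoxb1 and Anxa8. The count at an unadjusted p under 0.05 and at least 1.5-fold was 138 with the filter at the 50th percentile, 371 and 102 with offsets of 1 and 64, 399 with the neural tube covariate and 417 without control 1 and control 3, where the lone control was assumed to vary like the other arrays. The count of lists was between 9 and 14 except for 0 with an estimated correlation and 0 with directional fry, where 5 and 8 lists had an unadjusted p under 0.05. Of the 10 lists that passed, cell cycle and neural crest did not pass in 8 of 21 alternatives, periotic mesenchyme, WNT and hindbrain in 4, and hedgehog, BMP, endoderm and neurons in 2 (estimated correlation and directional fry), as did erythroid besides its turn given below. For hindbrain these included the covariate made from its own mean, which takes away its mean difference by construction. Of the 18 that did not pass, 10 passed in at least 1 alternative and 8 turned direction in at least 1. Calls over the list alone were kept 941 times and lost 443 times. The cause of these moves was not tested.

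The Tbx1 difference, which never passed, was 0.00045 with array weights and ranged from -0.14 to 0.10 when single arrays were left out, 0.04 without control 2 and 0.10 without Mest-KO 3. The erythroid list median ranged from -0.45 without Mest-KO 1 to 0.054 without Mest-KO 3. Pou3f2 and Olig3 were 0.10 and 0.051 with the neural tube covariate, Olig3 was 0.029 and Eif2s3y -0.0090 without control 1 and control 3. Pou3f2 and Olig3 belong to the neural tube list, whose own mean was the covariate. The differences of its members therefore average out by construction, and turned signs among them carry no information. The Y-linked difference between the groups, 0.33 on the log2 scale, was -0.16 with the neural tube covariate and -0.27 without control 1 and control 3, and kept its sign under the other alternatives run for it.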

Other observations

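All tests of explanations given here were chosen after the results were seen. Genes in this paragraph other than Mirg and Clu were chosen after their values were seen. Mirg lies in the imprinted Dlk1-Dio3 domain, which was not tested as a group. Of other genes of the domain, Meg3 read 1328 ± 371.9 in control and 2664 ± 493.9 in Mest-KO (log2 difference 1.02 ± 0.19, adjusted p = 0.0911), Dlk1 differed by 0.60 ± 0.12 (adjusted p = 0.112) and Rian by 0.34 ± 0.10 (adjusted p = 0.305). Imprinted genes outside the domain had log2 differences of 0.07 for Igf2, -0.02 for Cdkn1c, -0.11 for Peg3, -0.12 for Grb10 and -0.09 for Plagl1. All 4 probe sets of Clu were lower, by log2 differences of -1.32 to -1.54. Among probe sets without a single gene name, 2 passed the threshold, both lower in Mest-KO, by log2 differences of -1.44 ± 0.14 and -1.45 ± 0.21.

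The lower level of hindbrain neural tube genes may reflect how much neural tube each dissected piece held. The list mean ranged over 1.26 on the log2 scale within the control arrays alone, 1.29 times the difference between the groups. An effect of Tbx1 loss on these genes stays open, because the list means overlapped and 3 arrays against 3 cannot give an exact p below 0.1 (exact permutation p = 0.2).

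For the higher neuron list, with its median of 0.215, more ganglion neurons and more RNA of these genes per neuron cannot be told apart in pooled tissue. With the neural tube list as a covariate the median was 0.09, and 2 genes rose over the list alone where 9 had. The differences of those 9 genes were 0.27 to 1.57 times those before, with a median of 0.83. Their errors were a median of 1.42 times those before, so larger errors entered into the lost calls.

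Neural tube content stays open as an explanation of the lower hedgehog list. With the neural tube list as a covariate, the hedgehog list was past the threshold (adjusted p = 0.0070, though p = 0.0677 with an estimated correlation), but the 95% bootstrap interval of its median of -0.15 ran from -0.43 to 0.06, with genes resampled as if independent. Foxf2 went from -0.66 ± 0.16 to -0.33 ± 0.19, Shh from -1.50 ± 0.27 to -1.05 ± 0.35, Ptch1 from -0.25 ± 0.06 to -0.19 ± 0.09, Foxf1 from -0.96 ± 0.19 to -0.83 ± 0.27, Hhip from -0.92 ± 0.15 to -1.09 ± 0.22, Sostdc1 from -0.64 to -0.66 and Dhh from 0.53 to 0.54, so smaller differences and larger errors both entered where calls over the list alone ended, and Hhip alone of these 7 stayed past that threshold. Over all alternatives the adjusted p of the list ranged from 4.33e-05 to 0.176. A smaller amount of pharyngeal endoderm stays open: the 9 endoderm genes other than Shh and Foxa1 had a median of -0.149, but several of them are also made in other tissues. A fall of hedgehog signalling after Tbx1 loss also stays open. The 95% interval of Gli1 (-0.35 to 0.22, difference -0.068) included 0 and a fall of up to its lower limit. Gli1 was the only gene this test used. Of the other list members 6 fell and 1 rose over the list alone, with Ptch1 and Hhip among those that fell.

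The 10 ways of splitting the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 21 genes past the threshold and the highest of the others 0, so that 1 of the 10 splits, the real one, was as large. It gave 229 genes at an unadjusted p under 0.05 and at least 1.5-fold, against 166, so that again 1 split, the real one, was as large. It gave 10 lists past the threshold, against 11, so that 2 splits were as large, the real one and 1 other. The split with 166 genes and 11 lists put control 1, control 3 and Mest-KO 2 together, the 3 arrays with the highest neural tube level, and gave 0 genes past the threshold.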
